A study of Homo sapiens with 12 samples.

How the data were processed

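RNA of the colon cancer lines HT29, DLD1 and SW480 was measured on Illumina bead arrays with a single colour (Cy3), 1 array for each line and treatment: control, TSA, DZNep, and DZNep plus TSA. The deposited table of raw signals holds, for each of 22184 probes and 12 arrays, a mean bead intensity that the authors neither normalized nor corrected for background. The deposited detection p-value (p_value) of each probe, computed by BeadStudio, is the share of negative controls at or above its signal. BeadStudio is named in the submitters' notes without a version. The authors' processed values are a second deposited intensity, on a linear scale with 3410 to 3425 negative values per array. For the HT29 control array they equal the raw signal minus 106.2, and on every array their rank correlation with the raw signal is 1. Their medians lie between 71.42 and 71.46, so that each array was put on the scale of the HT29 control array by a curve whose method is not stated.

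Of the probes 19715 carried 1 gene symbol, 0 carried several and 2469 carried none; 19695 symbols were matched to current names in a RefSeq annotation. Arrays had a median of 41 to 43 beads per probe and 692 to 699 negative controls. Signals were corrected for background with normexp, the negative-control signals being inferred from the detection p (neqc of limma 3.58.1, R 4.3.3, offset 16), normalized between arrays by quantiles and put on a log2 scale. A probe was kept with a detection p under 0.05 on at least 3 of the 12 arrays, which left out 6392 probes and kept 15792. For the 1327 genes with several probes kept, the probe with the highest mean signal stood for the gene, which gave 12599 named genes and 1554 unnamed probes, 14153 in all.

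Samples were grouped by the labels, with cell line as the pair. Array profiles after removing treatment means correlated at 0.641 to 0.946 in the 18 pairs of 1 line, as checked on the data. They correlated at no more than -0.263 in the 36 pairs that differ in both line and treatment. Pairs that share a treatment were left out. A linear model with cell line and treatment (6 residual degrees of freedom) and moderated t-tests of limma gave each comparison of treatments and of lines, with p-values adjusted by Benjamini and Hochberg and a threshold of 0.05. The non-additive response is the combination minus TSA minus DZNep plus control. Differences of a response between lines were tested by an F test with 3 residual degrees of freedom, in a fit that assumes the responses to add up. The spread of the residuals was 0.237 for control, 0.269 for TSA, 0.239 for DZNep and 0.394 for the combination, while the model takes it as equal. 45 gene lists with 1412 entries, 1269 of them on the array and 1099 tested, were written from general knowledge and tested for 3 treatments against control with camera (preset correlation 0.01), adjusted over all lists and treatments. For a gene not detected in a group, a fold is given as a lower bound. The bound is computed on background-corrected signals, so it depends on that step.

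Genes named in the report follow a rule fixed before the data were examined. It takes the 10 largest rises and 10 largest falls that passed and went the same way in all 3 lines for each treatment against control, 5 of each for the other treatment comparisons, 6 per cell line, 8 genes always named, and up to 4 members of a list. The probes of a gene, the 9 arrays without the combination and the position and length of genes were looked at only after values had been seen. Probe pairs were compared by limma on the difference between the brightest and the second brightest probe of a gene.

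Tests were checked on simulated arrays with 200 changed genes of 14153 and the residual spread of the data. For DZNep they recovered 33% of 2-fold and 81% of 4-fold changes, for the combination 26% and 76%, for adding DZNep to TSA 37% and 86%, for adding TSA to DZNep 28% and 84%, and for the non-additive response 6% and 58%. Of 5 lists shifted by 0.5, 5 were recovered and 0 others called. Genes were simulated as independent of each other, so this does not tell how camera behaves where members of a list vary together. For comparisons of treatments each change was put in alike in all lines, with a spread equal for all treatments. Alternatives were no background correction, an offset of 50, scaling to the 75th percentile, the authors' values with a floor of 16, no filter, a detection p under 0.01, the mean of probes, an intensity trend with a robust prior, each line or treatment left out, no pairing, only the 6 arrays compared, an estimated correlation for camera, and fry. Permutations and odds ratios used Python 3.11.15 with scipy 1.17.1, statsmodels 0.14.6, numpy 2.4.6 and pandas 2.3.3, and figures matplotlib 3.10.9. Coordinates are not given, since the files name no genome build. Levels of genes that tell the sex of a donor were left out.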

Results

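Gene expression was measured in 3 human colon cancer cell lines, HT29, DLD1 and SW480, grown with trichostatin A (TSA), 3-deazaneplanocin A (DZNep), both drugs or neither. TSA inhibits histone deacetylases, and DZNep inhibits S-adenosylhomocysteine hydrolase (AHCY) and is known to deplete the Polycomb repressive complex PRC2. Each line gave 1 array per treatment, so that 12 arrays held 4 treatments with 3 arrays each. The labels give 200 nM TSA for HT29 and DLD1, 100 nM TSA for SW480 and 5 µM DZNep for all lines, and no doses for the combination. The arrays had a median raw intensity between 155.7 and 188.1 and a signal above the negative controls (detection p under 0.05) for 58.85% to 65.02% of the 22184 probes. DACT3, an inhibitor of Wnt signalling, was known beforehand as a gene picked from these arrays. The comparisons below ask which genes answer to each drug, to both, and to both beyond the sum of each.

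All values below are differences in log2 intensity, and all adjusted p-values are those of limma. Differences between treatments are means over the cell lines (n = 3 lines), and those between lines are averaged over the 4 treatments. Where an SE is given (±), it is that of the limma fit, which pools the residuals of all 4 treatments. This SE is not the spread of that comparison over the lines. With both drugs CCL20 had an SE of 0.70 and an SD over lines of 2.10, and PI3 had 0.42 and 0.29. The combination arrays had the widest residual spread (0.394), so the SE may be too small for them. The residuals measure the spread between 3 different cell lines, not between repeats of a treatment within a line. With TSA alone 0 of 14153 genes and unnamed probes passed, with DZNep 190 did, and with the combination 2581 did.

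**Figure D1:**
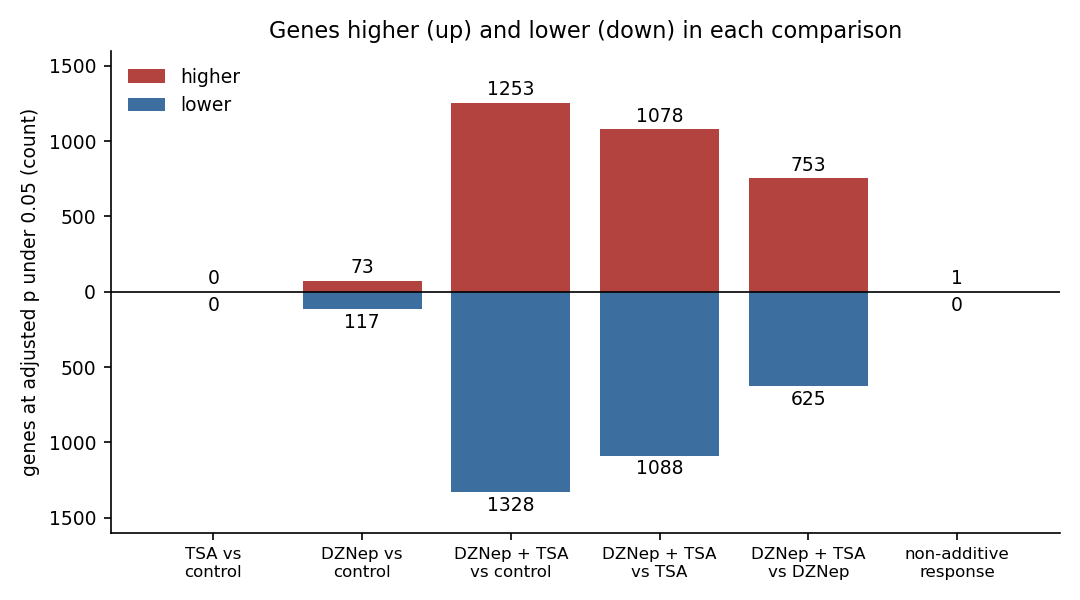
Number of genes at adjusted p under 0.05 in limma, higher above the zero line and lower below it, for each of 6 comparisons (x axis); the y axis is a count of genes. DZNep plus TSA against control gave 1253 higher and 1328 lower genes, TSA alone gave 0.

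TSA alone left the genes it was asked about near their control levels. DACT3 differed by 0.24 ± 0.32, the cell cycle inhibitor CDKN1A by 0.15 ± 0.29, the PRC2 methyltransferase EZH2 by 0.07 ± 0.25 and the Wnt target AXIN2 by -0.02 ± 0.46, and none of these passed the test. The histone genes, 31 of which were measured, had a median difference of 0.10, and 25 genes known to answer to histone deacetylase inhibitors had one of 0.18, with 0 members of either list passing over all genes or adjusted over the list alone. HBA1, which codes for alpha globin and is 1 of 13 blood cell markers, stood at 2.75 ± 0.43 with TSA, higher in 3 of 3 lines, which passed adjusted over that list alone (adjusted p = 0.00124) and not over all genes. HBA1 was detected on 2 of 3 control arrays, so this size may depend on the background correction. The number of genes at least 2-fold higher was 5 in HT29, 449 in DLD1 and 115 in SW480, and at least 2-fold lower 21, 268 and 91. In all, 1 gene was 2-fold higher and 0 were 2-fold lower in all 3 lines. Across genes, which are not independent replicates, the responses of the lines correlated at r = 0.05 (HT29 and DLD1), 0.17 (HT29 and SW480) and 0.07 (DLD1 and SW480). In limma 220 genes had an unadjusted p under 0.05, against 708 that chance gives. This fit takes the residual spread as equal, while it was 0.394 for the combination and 0.269 for TSA. On the 6 arrays compared alone the count was 866. It was under 708 in each other fit tried, such as 483 without the DZNep plus TSA arrays, a fit chosen after the data were seen. The count of 220 thus does not show that TSA changed fewer genes than chance gives. At adjusted p under 0.05 the count was 0 in each other fit tried. On simulated arrays the same test found 33% of the 2-fold and 86% of the 4-fold changes put in for this comparison. Those changes were alike in all 3 lines, so the shares do not tell how often a change that differs between lines is found.

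Of 45 gene lists fixed before the data were examined, 5 were called with TSA by camera, a test of a list against all other genes, at a preset correlation. The 40 measured genes of mitosis had a median of -0.41 (adjusted p = 1.13e-09; adjusted p = 0.818 with an estimated correlation), but the median was -0.35 in HT29, 0.40 in DLD1 and -1.17 in SW480, and without SW480 it was -0.003 with adjusted p = 0.998. CCNB1, a mitotic cyclin, stood at -0.77, 0.01 and -1.81 in HT29, DLD1 and SW480, and DLGAP5, a spindle protein, at -0.68, 0.28 and -1.89. The genes of cholesterol synthesis had a median of -0.31 (adjusted p = 0.000245; adjusted p = 0.745 with an estimated correlation), with CYP51A1 at -0.62 ± 0.25 and INSIG2 at -0.34 ± 0.15. The heat shock genes had one of -0.21 (adjusted p = 0.0123; adjusted p = 0.799 with an estimated correlation; adjusted p = 0.17 without DLD1), the interferon-stimulated genes one of -0.20 (adjusted p = 0.0287; adjusted p = 0.915 with an estimated correlation; adjusted p = 0.985 without HT29, 0.102 on the authors' values and 0.218 without pairing by line, no replicate block) and the neuronal genes one of 0.21 (adjusted p = 0.00106; adjusted p = 0.745 with an estimated correlation; adjusted p = 0.0658 without SW480). No member of these 5 lists passed the test on its own, over all genes or adjusted over the list alone. With treatments permuted within each line, as many lists as the 15 called over the 3 treatments were called in 92 of 100 draws, so the list calls here and below are not set apart from chance by that count.

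DZNep alone raised 73 and lowered 117 genes, 166 of them at least 2-fold. The largest rise was that of PI3, which codes for elafin, an inhibitor of elastase: 3.41 ± 0.42, or 10.6-fold (adjusted p = 0.00923). The forkhead factor gene FOXD4L1 rose by 3.13 ± 0.55, the nuclear membrane protein gene TMEM201 by 2.54 ± 0.50, the RAS-binding protein gene RASSF5 by 2.54 ± 0.21, the histone H3 gene H3C10 by 2.37 ± 0.39 and EID1, an inhibitor of differentiation that binds EP300, by 2.34 ± 0.18. FOXD4L1 and RASSF5 were detected on 1 of 3 control arrays each, so their sizes rest on the background step: without background correction FOXD4L1 stood at 1.89 (adjusted p = 0.0634) and RASSF5 at 1.32 (adjusted p = 0.0122). TAF5L, WWP2, ASPRV1 and GZF1 rose by 1.78 to 2.27. PI3 and ASPRV1 were detected on 2 of 3 control arrays, with control means of 5.72 and 6.04. Their sizes may thus depend on the background step too. ANKMY1 fell by 3.19 (SE 0.27, 9.13-fold), the inositol phosphatase gene INPP5A by 3.08 (SE 0.20), NKD2, a Wnt inhibitor that binds dishevelled, by 2.96 (SE 0.34), the vesicle transport gene TRAPPC12 by 2.93 (SE 0.23) and the opsin gene OPN3 by 2.92 (SE 0.31). ANKMY1 was detected on 2 of 3 DZNep arrays and stood at -1.97 without background correction (limma adjusted p = 0.0161). TBC1D22A, SLC44A3, LHPP, PANX2 and MOCOS fell by 2.23 to 2.72; the adjusted p-values of these 20 genes lay between 0.000555 and 0.0487.

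For 5 of these genes a second probe did not follow the first. The second probe stood at 0.20 for ANKMY1, 0.11 for INPP5A, -0.27 for RASSF5, 0.22 for TAF5L and -0.27 for WWP2, while TMEM201 and OPN3 had a second probe at 0.71 and -1.55. The second probes of ANKMY1, INPP5A, RASSF5 and WWP2 had mean levels of 5.32, 5.32, 5.38 and 5.51, near background, where a fall or rise can go unseen; that of TAF5L had one of 8.69. Among all 1327 genes with at least 2 probes that passed the filter, a test chosen after the data were seen found 43 whose brightest and second brightest probe answered differently to DZNep, against 0 for TSA (53 at an unadjusted p under 0.05, limma). Of genes named after their values were seen, INF2, a formin that shapes actin filaments, had one probe at -1.95 and the other at 2.37 (adjusted p = 3.55e-05), and the zinc transporter gene SLC39A3 had one at -0.44 and the other at 2.56 (adjusted p = 0.000967). BAIAP2, an actin regulator, had -2.09 and 0.92 (adjusted p = 0.0038), and RECQL5, a DNA helicase, -0.53 and 1.91 (adjusted p = 0.00545). In 20 of the 43 genes the probes moved in opposite directions in all 3 lines. Leaving out any 1 line gave a count of 8 such genes, and without the pairing by line (no replicate block) the count was 4.

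**Figure D2:**
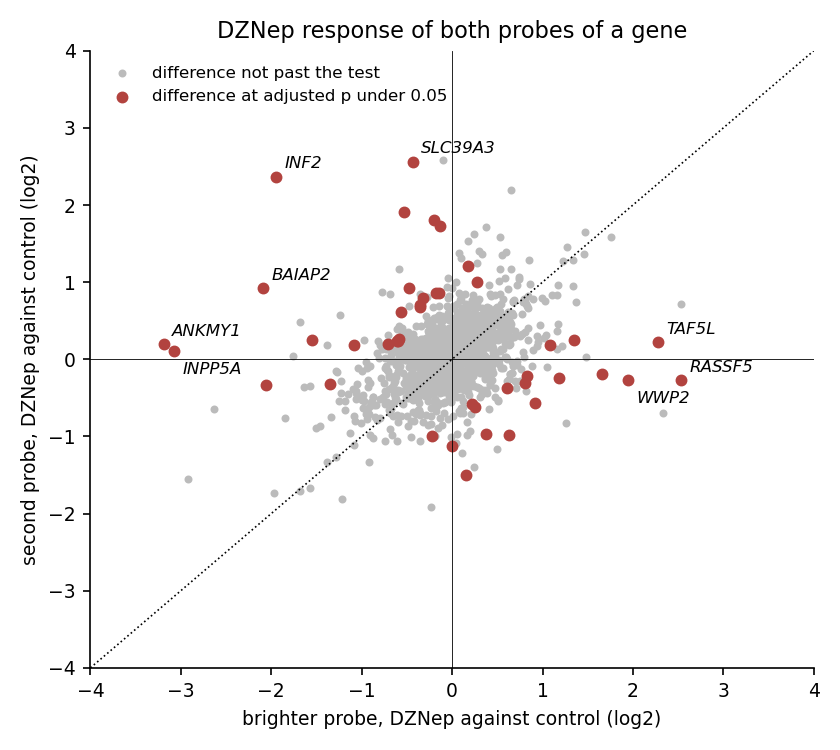
Difference between DZNep and control (log2, mean of 3 lines) at the brightest probe (x axis) and the second brightest probe (y axis) of 1327 genes, 1 point per gene; red points are the 43 genes whose probes differed at adjusted p under 0.05, and the dotted line is equality. INF2 lies at -1.95 on one axis and 2.37 on the other.

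Of the genes always named, none passed with DZNep alone. AHCY, the enzyme that DZNep binds, differed by 0.00 ± 0.17, EZH2 by -0.20 ± 0.25 and SUZ12 by 0.02 ± 0.20; EED had no probe. Of 10 PRC2 subunits 0 passed over all genes and 1 fell adjusted over the list alone, PHF1, at -0.87 ± 0.21 (adjusted p = 0.0807 over all genes). DACT3 was not detected in the DZNep arrays, so that no fold is given, and CDKN1A differed by -0.14 ± 0.29. MYC stood at 1.03 ± 0.57 (adjusted p = 0.435). Among 8 genes of earlier work on DZNep in breast cancer cells 0 rose and 1 fell, TGFBI, an extracellular matrix gene, by 1.09 (SE 0.20, adjusted p = 0.0377); adjusted over the list alone the counts were also 0 and 1. Of 64 developmental transcription factors known as PRC2 targets none passed over all genes or adjusted over the list alone, and of 12 PRC1 subunits only CBX7 did over all genes, which fell by 1.01 (SE 0.20, adjusted p = 0.0423); 2 fell adjusted over the list alone. Of 14 histone deacetylases and sirtuins 2 fell (3 adjusted over the list alone): SIRT5, a mitochondrial deacylase, by 1.46 (SE 0.25, adjusted p = 0.029), and HDAC6, named after its value was seen.

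Camera called 5 lists with DZNep, 3 higher and 2 lower. The 31 histone genes had a median of 0.51 (adjusted p = 0.000141; adjusted p = 0.745 with an estimated correlation). H3C10 alone rose over all genes, and 5 rose adjusted over the list alone. The 33 genes of ribosome biogenesis had a median of 0.46 (adjusted p = 2.3e-06; adjusted p = 0.818 with an estimated correlation). RRS1, an assembly factor of the large subunit, rose by 1.34 ± 0.24 (adjusted p = 0.0338), and 3 rose adjusted over the list alone. The NF-kB targets had a median of 0.43 (adjusted p = 0.0215; adjusted p = 0.842 with an estimated correlation; adjusted p = 0.215 without SW480), with 0 members passing over all genes and 2 adjusted over the list alone, the chemokine CCL20 at 2.69 ± 0.70 and TNFAIP3, an inhibitor of NF-kB, at 1.48 ± 0.39. The glycolysis and hypoxia genes had a median of -0.15 (adjusted p = 0.039; adjusted p = 0.745 with an estimated correlation; adjusted p = 0.13 without HT29, 0.0874 without SW480 and 0.0644 on the authors' values). The collagen hydroxylase gene P4HA1 fell by 1.19 (SE 0.19, adjusted p = 0.023), and 4 fell adjusted over the list alone. The cytosolic ribosomal proteins had a median of -0.15 (adjusted p = 0.0481; adjusted p = 0.915 with an estimated correlation; adjusted p = 0.0579 without DLD1, 0.348 without SW480, 0.282 on the authors' values and 0.0558 at a detection p under 0.01), and no member passed over all genes or adjusted over the list alone. Outside these lists, the heat shock factor gene HSF1 rose by 1.29 ± 0.24 (adjusted p = 0.0368) and CYCS, which codes for cytochrome c, by 1.37 ± 0.22 (adjusted p = 0.0247).

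The count of 190 for DZNep rested on all 3 lines: it was 3 without HT29, 0 without DLD1 and 0 without SW480 (1713, 1563 and 1415 at an unadjusted p under 0.05), and 0 without pairing by line (no replicate block, 578 at an unadjusted p under 0.05). It was 288 without background correction, 123 on the authors' values, 246 on the 6 arrays compared alone and, in a fit chosen after the data were seen, 679 without the DZNep plus TSA arrays.

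With DZNep and TSA together 1253 genes rose and 1328 fell, 1679 of them at least 2-fold. DACT3 rose by 5.67 ± 0.32, or 50.9-fold (adjusted p = 0.000161), with 4.89 in HT29, 6.0 in DLD1 and 6.12 in SW480. It was detected on 1 of 3 control arrays, so the size rests on the background step: it was 3.91 without background correction (adjusted p = 0.00145) and 7.01 on the authors' values. HBA1 rose by 4.94 ± 0.43, H3C10 by 4.70 ± 0.39, CCL20 by 4.52 ± 0.70, PI3 by 4.41 ± 0.42 and the histone H4 gene H4C8 by 4.38 ± 0.45. CNTNAP2, a neurexin-related gene of neurons, rose by 4.30 ± 0.72, HPCAL4, a neuronal calcium sensor gene, by 4.25 ± 0.58 and the dehydrogenase gene DHRS2 by 4.15 ± 0.53. CNTNAP2 and HPCAL4 were also detected on 1 of 3 control arrays and stood at 2.91 and 2.96 without background correction. HBA1, CCL20, PI3 and H4C8 were detected on 2 of 3 control arrays, with control means of 5.72 to 6.41. Their sizes may thus depend on that step too. LILRA3, a soluble receptor gene of leukocytes, was at least 10.4-fold higher in the mean (adjusted p = 0.0302), and was detected on 0 of 3 control and 2 of 3 combination arrays. This bound depends on background correction. The transporter gene ABCC3 fell by 3.75 (SE 0.50, 13.5-fold), EGFR by 3.69 (SE 0.60), and the insulin receptor substrate gene IRS1 fell by 3.64 (SE 0.72). ZMYM6 fell by 3.44 (SE 0.46) and the sulfatase gene ARSD by 3.34 (SE 0.27). ANKMY1, FERMT1, POGLUT3, SNTB1 and TBC1D22A fell by 2.95 to 3.28, and all these falls had adjusted p-values between 0.000847 and 0.0101. IRS1 and ANKMY1 were detected on 1 of 3 combination arrays and stood at -2.38 and -2.0 without background correction. EGFR stood at -1.12 and 0.44 at its other probes, ARSD at -1.49 and ANKMY1 at 0.01.

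**Figure D3:**
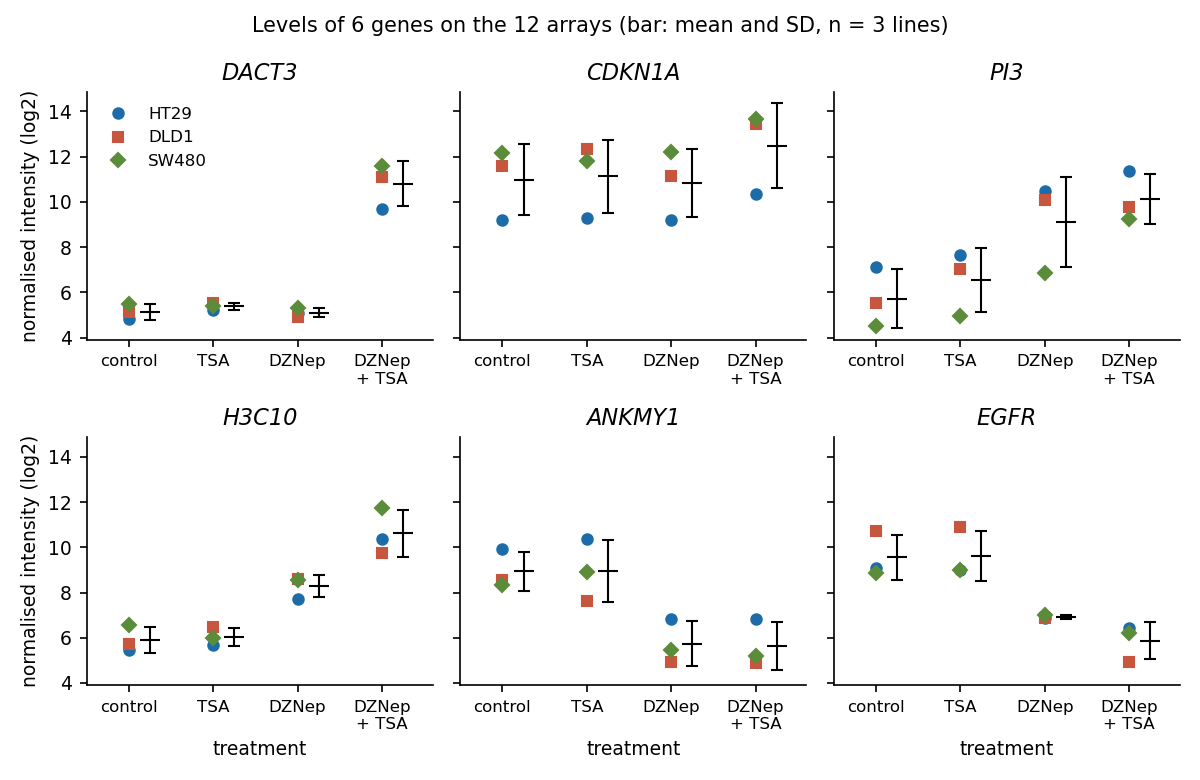
Normalised log2 intensity (y axis) of DACT3, CDKN1A, PI3, H3C10, ANKMY1 and EGFR on each of the 12 arrays by treatment (x axis); symbols are cell lines, and bars are the mean and SD over the 3 lines. DACT3 rose by 5.67 with both drugs (3.91 without background correction) and differed by 0.24 with TSA alone.

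Of the other genes chosen in advance, CDKN1A rose by 1.5 ± 0.29 with both drugs (adjusted p = 0.00924; 0.0518 without DLD1, 0.0809 without SW480, 0.0672 on the 6 arrays compared and 0.675 without pairing by line, no replicate block). The second probe of CDKN1A stood at 2.71 with both drugs and at 0.69 with DZNep, where the first stood at -0.14. EZH2 differed by 0.30 ± 0.25, SUZ12 by 0.03 ± 0.20 and AHCY by -0.16 ± 0.17, without passing. MYC stood at -0.65 in HT29, -2.61 in DLD1 and 0.70 in SW480, and AXIN2 at 0.49, -2.03 and -0.97 (adjusted p = 0.314 and 0.223).

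Most of the histone genes measured rose with both drugs. Of 31 measured 19 rose and 1 fell over all genes, and 23 rose and 2 fell adjusted over the list alone. The median was 1.79 (camera adjusted p = 1.46e-09; adjusted p = 0.745 with an estimated correlation). Besides H3C10 and H4C8, the histone genes H2AC18 and H2BC21 rose by 3.20 ± 0.33 and 2.97 ± 0.32. Of 40 neuronal genes 14 rose and 0 fell, over all genes and adjusted over the list alone, with a median of 0.77 (adjusted p = 0.000141; adjusted p = 0.745 with an estimated correlation). They held SYT11 and SYP, genes of synaptic vesicles, which rose by 2.47 ± 0.34 and 1.79 ± 0.38 (1.24 and 0.96 without background correction, each detected on 1 of 3 control arrays), and STX1A, a gene of vesicle fusion, which rose by 1.71 ± 0.35. Of 8 metallothioneins 2 rose over all genes, MT1G by 3.38 ± 0.70 and MT1X by 2.20 ± 0.40, and 5 adjusted over the list alone. The median was 1.24 (adjusted p = 0.0236; adjusted p = 0.745 with an estimated correlation; adjusted p = 0.126 without HT29 and 0.0558 at a detection p under 0.01).

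Some genes known as targets of Wnt signalling and markers of intestinal stem cells fell with both drugs. Of 30 Wnt targets 5 fell and 0 rose, over all genes and adjusted over the list alone, with a median of -0.84 (adjusted p = 0.0114; adjusted p = 0.745 with an estimated correlation), but the median was -0.14 in HT29, -1.77 in DLD1 and -0.68 in SW480, and -0.37 with adjusted p = 0.168 without DLD1. Of 16 stem cell markers 4 fell and 0 rose, over all genes and adjusted over the list alone, with a median of -0.77 (adjusted p = 0.0444; adjusted p = 0.745 with an estimated correlation; adjusted p = 0.182 without DLD1, 0.056 without background correction, 0.0512 with offset 50, 0.065 on the authors' values, and 0.183 without pairing by line, no replicate block). The lists share members: CD44, an adhesion receptor, fell by 2.19 (SE 0.30) and ASCL2, a transcription factor of crypt stem cells, by 2.38 (SE 0.41). Cyclin D1 (CCND1) fell by 1.48 (SE 0.33) and the AP-1 gene FOSL1 by 1.71 (SE 0.42), MYB by 2.07 (SE 0.40) and CDCA7 by 2.28 (SE 0.45). Of 34 inhibitors of the Wnt pathway DACT3 rose, and NKD2 fell by 1.99 (SE 0.34) and TLE5 by 0.70 (SE 0.21); adjusted over the list alone 1 rose and 1 fell. DACT3 had been picked from these arrays, so this list is not independent evidence, and it was not called (median 0.08, mean -0.02, adjusted p = 0.926).

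**Figure D4:**
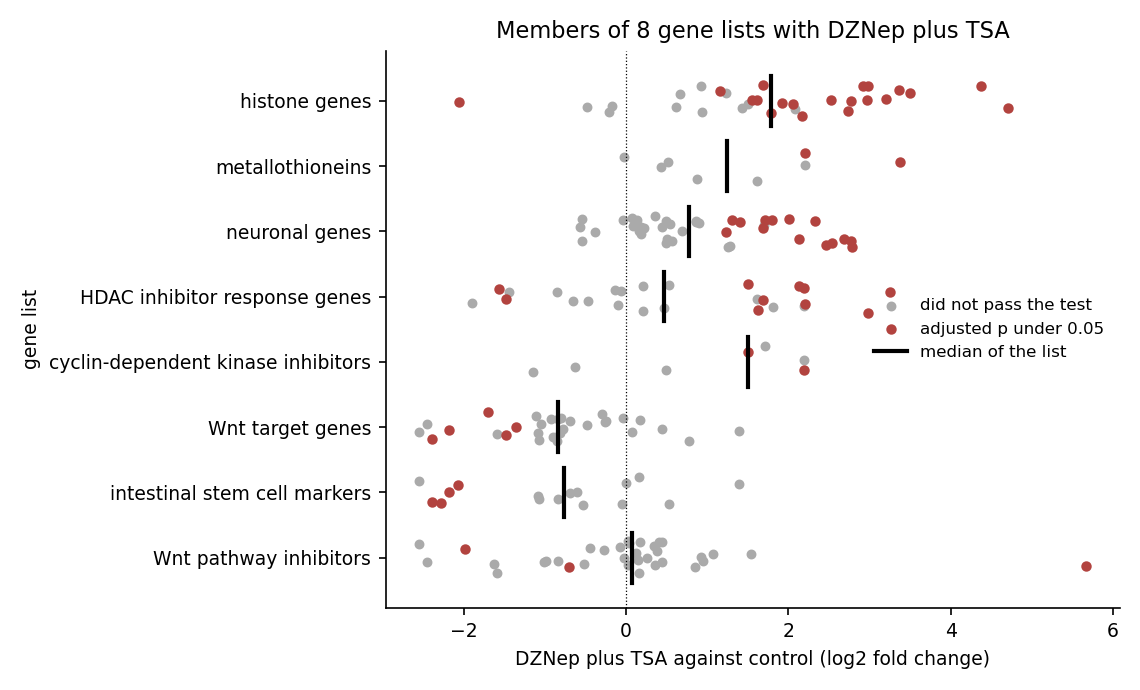
Log2 difference between DZNep plus TSA and control (x axis) for each measured member of 8 gene lists (y axis); red points passed at adjusted p under 0.05 over all genes, grey points did not, and the black bar is the median of the list. The histone genes have a median of 1.79 and the Wnt targets one of -0.84.

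Other lists held members that moved without a call of the list by camera. Over all 14153 genes and unnamed probes 1253 rose and 1328 fell, so that some members of any list are called. Of 25 genes known to answer to histone deacetylase inhibitors 8 rose and 2 fell (12 and 3 adjusted over the list alone; camera adjusted p = 0.0922). Of 7 inhibitors of cyclin-dependent kinases 2 rose, CDKN1A and CDKN2D, the latter by 2.19 ± 0.44 (4 rose and 1 fell adjusted over the list alone). Among 14 histone deacetylases and sirtuins SIRT4 rose by 2.52 ± 0.25, SIRT2 by 2.29 ± 0.44 and HDAC11 by 1.30 ± 0.24, and 2 fell (4 and 2 adjusted over the list alone). Of 10 PRC2 subunits 3 fell, PHF19 by 1.52 (SE 0.27), RBBP4 by 1.27 (SE 0.34) and AEBP2 by 1.07 (SE 0.18), and JARID2 rose by 1.01 ± 0.28; the counts adjusted over the list alone were also 3 and 1. PHC2 and CBX7 of PRC1 fell by 1.41 (SE 0.17) and 0.81 (SE 0.20), 2 of 12 over all genes and adjusted over the list alone. Of 64 developmental transcription factors known as PRC2 targets 5 rose and 0 fell (3 and 0 adjusted over the list alone). That share of rises was close to the one of all genes, 1253 of 14153, and does not set the list apart. For falls the list had 0 of 64, against 1328 of 14153. Among the 5 were the Notch target HEY1 by 2.86 ± 0.33 and the homeobox genes ISL1 by 2.60 ± 0.44 and MSX2 by 1.59 ± 0.33. Of 25 HOX genes 1 rose and 2 fell, over all genes and adjusted over the list alone, HOXB9 falling by 2.61 (SE 0.64).

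Genes of immunity went both ways. Of 20 antigen presentation genes 6 rose and 2 fell (7 and 2 adjusted over the list alone). ULBP2 and MICB, ligands of an activating receptor of natural killer cells, rose by 2.58 ± 0.42 and 1.60 ± 0.28, HLA-DMB rose by 2.25 ± 0.41 and the peptide loading gene TAPBP fell by 1.35 (SE 0.22), while its second probe stood at -0.16. Of 35 interferon-stimulated genes 0 rose and 5 fell (1 and 9 adjusted over the list alone), PARP9 by 1.99 (SE 0.31), the RNA sensor gene IFIH1 by 1.73 (SE 0.34) and MX1 by 1.62 (SE 0.42). The list was not called (adjusted p = 0.128), and its median was -1.29 in HT29 and 0.10 in SW480. Of 26 NF-kB targets 4 rose and 2 fell (5 and 2 adjusted over the list alone), TNFAIP3 rising by 2.24 ± 0.39 and LCN2, a secreted iron-binding protein gene, falling by 1.40 (SE 0.21). Of 25 p53 targets 4 rose and 1 fell, over all genes and adjusted over the list alone, TIGAR rising by 1.36 ± 0.25 and ZMAT3 by 1.25 ± 0.23. Of 31 pro-apoptotic genes 5 rose and 4 fell (9 and 6 adjusted over the list alone), with CYCS at 2.14 ± 0.22 and BID at -2.39 ± 0.47, and of 14 anti-apoptotic genes 1 rose and 3 fell over all genes and adjusted over the list alone, CFLAR falling by 2.56 (SE 0.46). Among 35 genes of epithelial adhesion and keratins 1 rose and 5 fell (1 and 6 adjusted over the list alone), with the splicing factor gene ESRP1 falling by 1.03 (SE 0.25; -0.46 without background correction) and the tight junction gene CLDN2 by 2.58 (SE 0.66). MMP9 and SNAI1 of 11 mesenchymal markers rose by 2.47 ± 0.28 (1.35 without background correction) and 2.34 ± 0.31, 2 and 0 over all genes and adjusted over the list alone. Of 13 blood cell markers 3 rose, the globins HBA1 and HBB (at least 8.38-fold) and the actin regulator CORO1A by 1.70 ± 0.33 (4 adjusted over the list alone). The bound for HBB depends on background correction.

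Leaving out 1 line moved the count of the combination from 2581 to 2215 without HT29, 571 without DLD1 and 280 without SW480. Without pairing by line (no replicate block) it was 66, and 26 on the 6 arrays compared alone. The combination arrays had the widest residual spread (0.394), so a residual shared by all arrays may call too many genes here. With scaling to the 75th percentile in place of quantile normalization the median of all genes moved by 0.18, and 62.7% of 3255 called genes were higher, against 48.5% here.

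What DZNep added to TSA and what TSA added to DZNep were compared directly. On top of TSA, DZNep raised 1078 and lowered 1088 genes, and on top of DZNep, TSA raised 753 and lowered 625. DACT3 rose in both, by 5.43 ± 0.32 over TSA alone (adjusted p = 0.000242) and to a level at least 39.8-fold above the background-corrected signal with DZNep alone (adjusted p = 0.000152). Without background correction the differences of DACT3 were 3.80 and 3.92, so that this bound holds only with it. The labels give no doses for the combination, and these comparisons read as added drugs only if the doses were those of the single treatments. DZNep on top of TSA also raised CCL20 by 4.59 ± 0.70, H3C10 by 4.57 ± 0.39, CYSRT1 by 4.01 ± 0.57 and CNTNAP2 by 3.76 ± 0.72. EGFR fell by 3.77 (SE 0.60), ABCC3 by 3.74 (SE 0.50), and ARSD by 3.41 (SE 0.27). IRS1 fell by 3.33 (SE 0.72) and ANKMY1 by 3.32 (SE 0.27). Without background correction IRS1 stood at -2.15 and ANKMY1 at -2.07. TSA on top of DZNep raised HBA1 by 4.83 ± 0.43, the secretoglobin gene SCGB2A1 by 4.50 ± 0.71, HPCAL4 by 4.20 ± 0.58 and DHRS2 by 3.92 ± 0.53. The integrin activator gene FERMT1 fell by 2.83 (SE 0.38), ZMYM6 by 2.80 (SE 0.46), and CLDN2 by 2.78 (SE 0.66). The stress gene NUPR1 fell by 2.71 (SE 0.63) and the phosphodiesterase gene PDE4D by 2.55 (SE 0.64). SCGB2A1, detected on 1 of 3 DZNep arrays, stood at 3.03 without background correction. CCL20 and CNTNAP2 were detected on 2 of 3 TSA arrays, and HPCAL4 and DHRS2 on 2 of 3 DZNep arrays. Their sizes may thus depend on that step too. CDKN1A rose in both, by 1.35 ± 0.29 and 1.64 ± 0.29 (adjusted p = 0.0157 and 0.0155). The first was lost without SW480 (adjusted p = 0.19) and on the 6 arrays compared (0.128), the second without DLD1 (0.0774), without SW480 (0.155) and on the 6 arrays (0.0861), and both without pairing by line, no replicate block (0.784 and 0.747). For DACT3 the adjusted p of adding DZNep to TSA was 0.118 on the 6 arrays compared.

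The response to DZNep could be compared with what it added to TSA, since these differences share no array. Both were tested with the same residual spread of each gene, which by itself makes shared calls more likely. The numbers for independent lists below may therefore be too low. Of the 73 genes that DZNep raised 46 also rose when it was added to TSA, against 5.56 if the lists were independent, and of the 117 that it lowered 86 also fell, against 8.99; 0 went opposite ways. Across all genes the correlation was r = 0.48 for DZNep and 0.29 for TSA, and about 0 in simulated arrays without an effect. Leaving out 1 line moved the count for adding DZNep from 2166 to 1877 without HT29, 689 without DLD1 and 12 without SW480, and that for adding TSA from 1378 to 1037, 92 and 1. Without pairing by line (no replicate block) the counts were 34 and 6, and on the 6 arrays compared alone 0 (2719 at an unadjusted p under 0.05) and 6.

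DACT3 was the single gene whose response to both drugs passed as different from the sum of the responses to each, which also rests on equal doses. Its fitted excess was 5.47 ± 0.46 (adjusted p = 0.00566). Since DACT3 was detected on 0 of 3 DZNep and 1 of 3 control arrays, this size depends on the background step and is no exact difference. The adjusted p was 0.0149 without HT29, 0.189 without DLD1, 0.741 without SW480 and 0.121 without background correction, with an excess between 3.81 and 6.11 in these 4 fits. CDKN1A had an excess of 1.49 ± 0.41 (adjusted p = 0.228) and MYC one of -2.09 ± 0.81 (adjusted p = 0.3), and neither passed. In all, 2010 genes had an unadjusted p under 0.05, against 708 expected by chance. That count was 1934 without HT29, 1807 without DLD1 and 713 without SW480, the last near the number that chance gives. It was 415 without pairing by line (no replicate block), 2003 without background correction and 1884 on the authors' values. The excess over chance thus does not hold in every fit, and leaving out a line also leaves fewer residual degrees of freedom.

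Each pair of lines differed at 5729 to 6127 genes, averaged over the 4 treatments. HT29 stood apart by TM4SF4, at least 224-fold above DLD1 and at least 254-fold above SW480, the retinal dehydrogenase gene ALDH1A1, by 8.0 ± 0.30 log2 units over DLD1, the lysozyme gene LYZ, the lactate receptor gene HCAR1, the stem cell surface gene PROM1 and the mucin glycosylation gene GCNT3. DLD1 stood apart by TMEM200A, at least 70.5-fold above HT29, the termination factor gene GSPT2, the chemokine gene CXCL5, ID3, an inhibitor of basic helix-loop-helix factors, and NLRP2, while 1 further gene that met the rule is not named here. SW480 stood apart by the glucose transporter gene SLC2A3, whose mean of 15.81 lay near the top of the range, so that no exact difference is given, by NELL2, at least 190-fold above DLD1, and by KRT5, STC2, KIF1A and the Hedgehog effector gene GLI3. The largest adjusted p among these genes was 1.96e-05 (n = 4 arrays per line). The lower bounds of folds were computed on background-corrected signals and depend on that step. Each line was hybridised on a slide of its own, so line and slide cannot be told apart. Without the control arrays the count between DLD1 and SW480 was 3636 in place of 5729, and without the DZNep arrays 3808.

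Whether a drug acted differently in the lines was tested with 3 residual degrees of freedom. No gene passed for TSA (222 at an unadjusted p under 0.05, limma) or for DZNep (1205), in any fit tried. On simulated arrays this test found 5% of 4-fold and 70% of 32-fold differences for TSA, and 3% and 64% for DZNep. SW480 was given another TSA dose than the other lines, so line and dose cannot be told apart.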

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

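The tests of the TSA arrays without the combination and of TSA responses that differ between lines were chosen only after the result was seen, as were the minimums of 0.5 for a gene and 0.25 for a list below.

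The SW480 array with DZNep plus TSA stood apart from the other 3 SW480 arrays in the error of its beads: the median standard error was 4.531% of the signal, against 4.103% to 4.169%. NELL2, a secreted protein gene that marks SW480, was at 13.7 with DZNep in SW480 and at 12.87 to 12.91 on the other 3 arrays of the line. Of 26 groups of 4 arrays tested in this way 2 had such an array, and chance alone gives 1.3.

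MYC went opposite ways in the lines with DZNep plus TSA, with -2.605 in DLD1 and 0.702 in SW480. The mitosis genes did so with TSA, with a median of -1.167 in SW480 and 0.395 in DLD1. Neither the difference of MYC with the combination nor that of the list median with TSA was tested. Gene by gene, the limma test of TSA responses between lines called 0 genes, mitosis genes included (222 at an unadjusted p under 0.05), and SW480 was given another TSA dose. Among the 6392 probes left out as too dim, 113 were detected on 2 DZNep plus TSA arrays and on no other array, against 16 for control, 9 for TSA and 8 for DZNep.

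TSA called 0 genes, although DLD1 had 449 genes 2-fold higher and HT29 had 5, among genes detected on either array. The wide spread of the combination arrays was tested as a cause by leaving them out: the limma count for TSA was still 0 (483 genes at an unadjusted p under 0.05), while that for DZNep went to 679. A failed TSA treatment of HT29 alone would leave DLD1 and SW480 alike only if both lines answer alike to TSA. SW480 was given 100 nM TSA and DLD1 200 nM. Of 719 genes at least 2-fold changed by TSA in DLD1, 56.3% moved the same way in SW480 and 53.7% in HT29. They were counted without asking for detection in DLD1. For DZNep 81.4% of 1540 such genes moved the same way in SW480. With unlike doses, these shares cannot tell whether the treatment of HT29 failed. A response that differs between the lines, a biological explanation that the design names, stays open: the test of the difference called 0 genes, in a design that found 5% of simulated 4-fold differences. It cannot be told apart from noise of single arrays or, for SW480, from its dose.

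Other splits of the arrays were counted for each result. For comparisons of 3 with 3 arrays there are 10 splits, too few for a share under 0.05. The real split gave 190 genes for DZNep, 2581 for the combination, 2166 for adding DZNep to TSA and 1378 for adding TSA to DZNep, and 43 and 126 genes whose probes moved apart with DZNep and the combination; the highest of the other splits was 0 in each, and in each 1 of the 10 splits, the real one, reached the real count. For TSA the real split and all others gave 0, for genes and for probes, so that 10 of 10 did. Of the 10 splits 4 part all 3 pairs of arrays, and the 3 others of these gave at most 0, as did those that part 1 pair. Every other split mixes arrays of both treatments, so that effects of a drug widen its residuals. Its low counts were therefore set in advance and do not test chance.

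Between cell lines 1 of 35 splits, the real one, reached 6066, 6127 and 5729 genes, and the highest of the others was 1, 0 and 3. Every other split mixes arrays of both lines, so that differences between the lines widen its residuals. Low counts there were thus set in advance, and the splits do not test chance. For the non-additive response chance cannot be excluded, since 5 of 100 permutations within lines, the real one included, gave at least 1 gene, and the highest of the others gave 11. For gene lists it cannot either: 92 of 100 gave at least the 15 lists of the real labels, and the highest gave 36, while in both cases permuted labels still carry real effects of the drugs. For differences of the TSA and DZNep responses between lines all 100 of 100 gave at least 0 genes, and the highest of the others was 0.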

How the results depend on the processing

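The fit without the DZNep plus TSA arrays and all counts of probe pairs were chosen only after the data were seen.

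TSA gave 0 genes in every fit. Of results for genes that were called, 1726 kept their direction and side of the threshold and 716 were no longer past it, none with a change of direction; all 221 for line markers kept both. Of results for genes not called 2641 stayed, 28 moved and 47 came past the threshold. Of results for called gene lists 131 kept both, 48 were no longer past the threshold and 1 vanished: the median of the mitosis genes with TSA was -0.003 without SW480 (range -0.768 to -0.003 without 1 line), where only the direction of the camera test, at adjusted p = 0.998, was the opposite. Of counts 140 stayed within 1.5 times the reported one and 36 did not.

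Without background correction DZNep gave 288 genes and the non-additive response 0. On the authors' values they gave 123 and 4, and probes moved apart with DZNep in 27 genes. Without pairing by line (no replicate block) DZNep gave 0, the combination 66, adding DZNep to TSA 34 and adding TSA to DZNep 6, and probes moved apart in 4 genes with DZNep and 2 with the combination: differences between lines then count as noise. With only the 6 arrays compared the combination gave 26, adding DZNep to TSA 0 and adding TSA to DZNep 6, with fewer residual degrees of freedom. Without the DZNep plus TSA arrays DZNep gave 679. Lists numbered 26 with scaling to the 75th percentile, 0 with an estimated correlation and 7 with fry. The cause was not tested unless named.

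Leaving out 1 line, the counts ranged from 0 to 3 for DZNep, 280 to 2215 for the combination, 12 to 1877 for adding DZNep to TSA, 1 to 1037 for adding TSA to DZNep, 0 to 1 for the non-additive response and 17 to 20 for lists. For probes they were 8 for DZNep and 3 to 87 for the combination. Leaving out 1 treatment, DLD1 and SW480 differed at 3636 to 6381 genes. Fewer arrays leave fewer residual degrees of freedom. Signal over background limits dim genes: 6392 probes were not tested, and DACT3 with DZNep has only a bound.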

Other observations

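The 3 tests of probe pairs were chosen only after the result was seen, as were the comparisons of gene length; of the tests of chromosome ends the rotation was too, and the others were written before their results, on a pattern noticed among named genes.

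INF2, RECQL5 and BAIAP2 are examples of 43 genes whose probes moved apart with DZNep. Dim probes as the whole cause are argued against: 58.1% of these genes had both probes detected on all 12 arrays, against 49.1% of all genes with 2 probes. A candidate explanation is that DZNep moves transcripts of 1 gene in opposite ways. In 20 of the 43 genes the probes moved in opposite directions in all 3 lines. When DZNep was added to TSA, on arrays not used in the first comparison, the difference had the same sign in 95.3% of genes (41 of 43). Its median was 1.08 in the direction of the first. That shows that the difference repeats, and does not tell its cause. A second probe near background or a probe assigned to another gene would give that too. A probe assigned to another gene stays open. The differences between lines at the 2 probes correlated at 0.277 (bootstrap range 0.0399 to 0.486), below the 0.321 that 2.5% of random sets fall under.

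Genes lowered by DZNep lay near a chromosome end, within 50 genes of it, more often than others: 27.6% of 105 against 10.3% (odds ratio 3.31, Fisher's exact p = 6.82e-07; 24.2% and exact p = 0.000115 without the 10 named falls, such as ANKMY1 and INPP5A, among which it was noticed). Gene length and level as the whole cause are argued against. The set without the 10 named falls had an odds ratio of 2.77 on its own. With length, level and the number of measured genes on the chromosome in the model it was 2.93 (95% interval 1.79 to 4.78). Which chromosome a gene lies on was not in the model. A shift of every gene near an end is argued against too: uncalled genes there differed from other uncalled genes by a median of 0.0075 (permutation p = 0.586). For the 95 genes beyond the named falls chance is argued against too: 23 lay near an end, and with the calls rotated along the gene order, which keeps neighbours together, a share of 0.000241 of 12468 rotations gave as many. The test of chance written beforehand used 906 other genes, lowered by adding DZNep to TSA and not by DZNep. Of these 11.8% lay near an end, against 10.2% (Fisher's exact p = 0.14), the outcome foreseen for chance. The rotation, chosen afterwards, covers only the 95 genes, so whether the pattern reaches other genes stays open. Of all 984 lowered by adding DZNep to TSA, those of the pattern included, 13.3% lay near an end (Fisher's exact p = 0.00335). GC content could not be tested and stays open, and no biological explanation was tested.

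Genes that rose with DZNep were short and those that fell were long, with a median of 12.2 kb for 65 genes (permutation p = 1e-05) and 45.6 kb for 105 (permutation p = 3e-05), against 28.3 kb for uncalled genes. With DZNep plus TSA the medians were 20.9 kb and 36.9 kb against 28.1 kb (permutation p = 1e-05 for each, the smallest that 100000 permutations can give).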
